A study of Mus musculus with 20 samples.

How the data were processed

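Total RNA from hippocampus and amygdala of mice at postnatal day 21 was measured by RNA sequencing in 20 libraries, 10 per tissue. The RNA was extracted with a lipid tissue RNeasy kit and the libraries were made with a TruSeq stranded mRNA kit, per the labels' protocols. Each tissue had 4 control, 3 NCoR1-KO and 3 SMRT-KO libraries. The knockouts combine a pan-neuronal Cre driver, Snap25-IRES2-cre, with floxed alleles, of Ncor1 in NCoR1-KO. Some results are not reported here. The labels do not say whether the control animals carried Cre or floxed alleles. They also do not say that the libraries of a group come from separate animals, so all p-values measure the spread between these samples, which may be in part technical.

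The deposited tables hold gene-level TPM values (a unit scaled for transcript length and for the total of each library) made by the authors. Per the submitters' processing notes, the tools were bcl2fastq, fastp 0.21.0, STAR 2.5.3a and RSEM 1.3.3 and the genome build was mm10. The notes give these names and versions with no role or order. The gene annotation is not given in the sources used here. Each tissue has its own table of 23412 gene symbols, with values rounded to 2 decimals and a total between 999999 and 1000001 per library. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting error can be attached to a value. All 20 columns named a labelled sample, and 0 columns of other samples were used.

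Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1. A gene was tested in a tissue when it reached 1 TPM in at least 3 of the 10 libraries, whatever their genotype. A linear model with the 3 genotypes as groups was fitted to all 10 libraries of a tissue, with moderated variances and a trend of the variance with expression. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with 0.05 as the threshold. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes of low expression, and are given with the standard error of the model. Means of TPM are given with the standard deviation over libraries. Differences between tissues in a knockout effect were tested in a joint fit of all 20 libraries over the genes that passed the filter in both tissues, with the libraries taken as unpaired. The levels of Ncor1 and Snap25 were also compared by a two-sided exact permutation test of log2 values. With 3 against 4 libraries this test has 35 arrangements and a smallest possible p of 0.0286.

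A collection of 41 gene lists with 654 symbols, covering hormone response, neuronal function, metabolism, stress, cell types and neighbouring brain regions, was written from general knowledge. Genes with a span longer than 100 kb formed 1 further list. Lists with at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01 between genes, and again with a correlation estimated from the residuals. P-values were adjusted over the lists of a comparison. Within a list, genes were counted as changed over all tested genes and as changed when adjusted over the list alone. A library's score for a list is the median, over the list's genes, of the log2 deviation from the gene's mean over the tissue. Mitochondrially encoded genes were not listed in the tables used here.

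Gene positions, spans and transcript lengths are from GENCODE M21, on the GRCm38 assembly that mm10 names. Of the 23412 symbols, 21739 matched a gene symbol and 1272 an older symbol of a single gene, 41 named several genes and 360 had no match. Transcript length is that of the longest coding transcript. Genes that overlap another gene on the same strand are uncertain, since reads there can be assigned to either.

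Genes are named by a rule. Ncor1 is named throughout. For each knockout against control, these are the 6 highest and 6 lowest fold changes among genes that passed and whose knockout and control libraries did not overlap. Where fewer than 6 passed in a direction, all that passed are named, then genes of smallest unadjusted p up to 4, given as values that did not pass. From each list that camera called, up to 4 members of smallest p could be named. Up to 8 genes that passed in both tissues or in both knockouts are named, and the 4 of smallest p per direction in the comparison of the knockouts and in the differences between tissues. Predicted genes and sex-linked genes are counted and not named. Snap25 in the comparison of the knockouts was named after its values were seen. The groups, tests, lists, naming rule and a first set of alternatives were fixed before the data were examined.

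Fold changes of both knockouts share the same controls, so their correlation was set beside 100 simulations of unchanged groups and beside values with the 4 controls divided between the knockouts. Changed genes within 10 Mb of Ncor1 were compared with other genes by a two-sided Fisher's exact test, with windows of 5 and 20 Mb as alternatives. The first set of alternatives held a pseudocount of 0.1, no filter, a filter at a mean of 5 TPM, quantile normalization, median ratio scaling, a robust variance estimate, the replicate number as a block, a fit of only the groups compared, an estimated correlation in camera, and each library left out in turn. Chosen after seeing the data were the removal of a smooth trend with transcript length and GC content (natural splines with 4 degrees of freedom), the omission of control 1 in both tissues, the omission of hippocampus SMRT-KO 2 and 3, and scores of 3 marker lists as covariates. The samples were also regrouped in every possible way or in 100 seeded ways, and for the agreement between tissues, after the results were seen, alike in both tissues.

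The fit was tested on simulated data for NCoR1-KO against control, with 200 changed genes in each of 5 simulations. Changes of 0.5, 1 and 2 on the log2 scale were called in 49.3%, 82.4% and 97.9% of cases among the 14501 hippocampus genes and in 67.2%, 89.6% and 99.4% among the 14606 amygdala genes. The noise was drawn separately for each gene, and the microglia genes were also raised by 0.5 in NCoR1-KO. In real libraries genes can deviate together, so these shares need not hold there. A real count of 0 called genes therefore does not exclude changes of these sizes.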

Results

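NCoR1 and SMRT are corepressors that bind nuclear receptors, among them the receptors for thyroid hormone, and recruit histone deacetylase complexes. The design asked how gene expression in the young brain differs when neurons lose either protein. Hippocampus and amygdala were taken from mice at postnatal day 21, and each tissue gave 4 control, 3 NCoR1-KO and 3 SMRT-KO libraries. Between 13787 and 14391 genes reached 1 TPM in a hippocampus library and between 14153 and 14509 in an amygdala library. The depth of each library is unknown, since TPM keeps none. Log2 values correlated across genes, which are not independent replicates, with r from 0.970 to 0.993 between hippocampus libraries and from 0.973 to 0.995 between amygdala libraries. The ribosomal RNA precursor Rn45s took 1.87% to 3.28% of the TPM in hippocampus controls, 1.04% to 1.66% in NCoR1-KO and 0.953% to 1.55% in SMRT-KO, so every hippocampus knockout library lay below every control. In amygdala it took 1.25% to 2.15%, 1.23% to 1.49% and 1.77% to 3.27%. Xist, the RNA of the inactive X chromosome, lay between 0.01 and 0.05 TPM in all 20 libraries, and the Y-linked Ddx3y between 37.9 and 66.4 TPM.

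Ncor1 lies on the minus strand of chromosome 11 from 62316426 to 62458541 (GRCm38). In hippocampus its level was 41.9, 44.5 and 61.1 TPM in NCoR1-KO 1, 2 and 3 and 81.6, 119, 129 and 137 TPM in controls 1, 2, 3 and 4. In amygdala it was 32.1, 34.6 and 39.0 TPM in NCoR1-KO 1, 2 and 3 and 71.3, 117, 119 and 127 TPM in controls 1 to 4. Ncor1 fell in amygdala NCoR1-KO to 32.5% of control, from 108 ± 25.1 TPM (SD, n = 4) to 35.2 ± 3.51 TPM (SD, n = 3), a log2 change of -1.57 ± 0.16 (SE) with limma's adjusted p = 0.00732. Without NCoR1-KO 2 the change was -1.56 with adjusted p = 0.0541. In hippocampus NCoR1-KO the level was 42.1% of control, 49.2 ± 10.4 TPM against 117 ± 24.7 TPM, with a log2 difference of -1.22 ± 0.20. It did not pass over all genes (adjusted p = 0.79). It passed when adjusted only over the list of NCoR/SMRT corepressor complex genes (adjusted p = 0.00131), a short list written to include Ncor1. A two-sided exact permutation test in hippocampus gave p = 0.0286, the smallest that 35 arrangements allow. In SMRT-KO, Ncor1 was at 101 to 143 TPM in hippocampus and at 114 to 124 TPM in amygdala. Its log2 differences from control were 0.02 ± 0.20 and 0.16 ± 0.16 (exact permutation p = 0.914 and p = 0.857). Without control 1 these 2 differences were -0.14 and -0.03.

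Snap25, a synaptic vesicle fusion protein whose locus carries the Cre driver (plus strand of chromosome 2, 136713453 to 136782428), was lower in every knockout library than in any control. In amygdala it fell from 2033 ± 189 TPM in controls to 1184 ± 54.4 TPM in NCoR1-KO and 1125 ± 77.3 TPM in SMRT-KO. The log2 changes were -0.78 ± 0.08 (adjusted p = 0.00732) and -0.85 ± 0.08 (adjusted p = 0.00507). Those calls ended without NCoR1-KO 2 (adjusted p = 0.0541) and without SMRT-KO 3 (adjusted p = 0.0687). In hippocampus the means were 2255 ± 53.1, 1292 ± 47.4 and 1345 ± 316 TPM in control, NCoR1-KO and SMRT-KO. The differences of -0.80 ± 0.12 and -0.77 ± 0.12 did not pass over all genes. Without hippocampus SMRT-KO 3 the second was -0.95 with adjusted p = 0.00249.

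**Figure D1:**
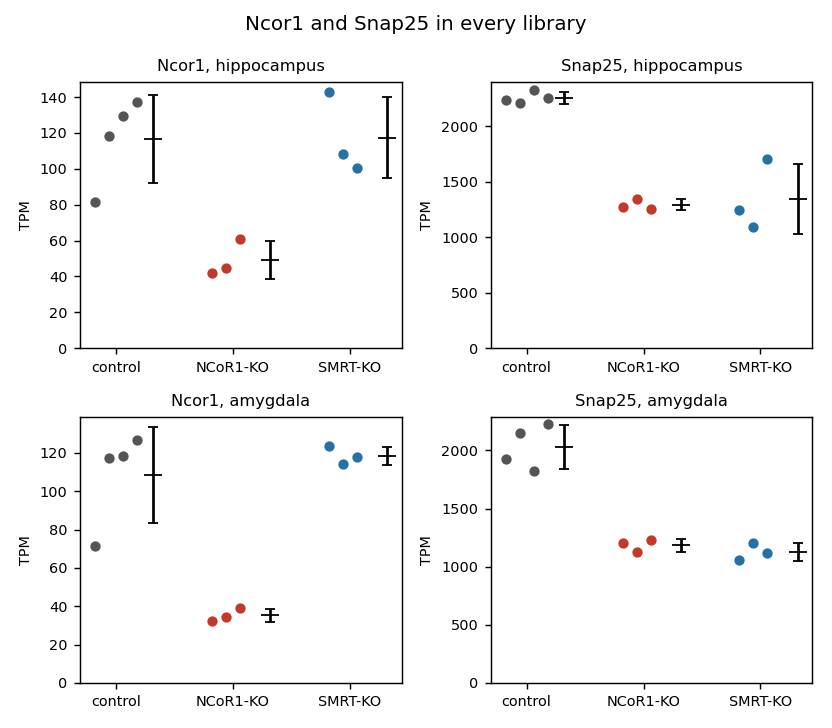
TPM (vertical axis, from 0) of Ncor1 and Snap25 in each control, NCoR1-KO and SMRT-KO library of hippocampus and amygdala; points are libraries and black bars are mean ± SD. Snap25 lies at or below 1699 TPM in every knockout library and at or above 1825 TPM in every control, while the Ncor1 level of control 1 stands below the other controls in both tissues.

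In hippocampus NCoR1-KO no single gene passed. At the preset correlation, the lists of immediate early, of heat shock and acute stress, and of circadian clock genes lay above control as groups. Neuropeptide and interneuron genes lay below, and all these calls ended with an estimated correlation (smallest adjusted p = 0.474). The neuropeptide and interneuron calls also ended without control 2 (adjusted p = 0.0579 and adjusted p = 0.0588). Arc, an activity-induced synaptic gene, was at 164 ± 37.3 TPM against 104 ± 40.3 TPM in control (log2 difference 0.70 ± 0.27, n = 3 against 4), and Egr3 differed by 0.32 ± 0.12. Arntl, a core clock activator, was at 33.2 ± 1.64 against 27.3 ± 1.87 TPM, and Nfil3, a clock-controlled repressor, differed by 0.55 ± 0.15. Gad2, which makes GABA, was at 87.1 ± 13.7 against 125 ± 20.8 TPM (-0.51 ± 0.15). Limma called 0 of 14501 genes. There were 658 at an unadjusted p under 0.05, 273 higher and 385 lower, and the smallest adjusted p was 0.79. The knockout and control libraries did not overlap for 1173 genes, 8.09% of those tested, where chance gives 5.71%. The chance share is an average over all splits of the libraries. Genes that move together can take a single split far from it, here and in the other comparisons. Of the genes nearest to passing, Bcl6 was at 59.3 ± 2.99 against 44.8 ± 0.554 TPM (0.40 ± 0.07, adjusted p = 0.885). Cxcr7, Parp1 and Nutf2 differed by 0.43 ± 0.10, 0.26 ± 0.06 and 0.24 ± 0.06. S100a10 was at 29.6 ± 3.31 against 43.7 ± 2.14 TPM (-0.55 ± 0.10), and Tcp11l1 differed by -1.22 ± 0.25. The count was 1, Snap25, without hippocampus SMRT-KO 3 or without hippocampus SMRT-KO 2 and 3, and 1 predicted gene without control 2. Snap25 was also named by the rule here, among the lower genes nearest to passing.

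Camera called 16 of 41 gene lists in this comparison at the preset correlation and 0 with an estimated correlation. Heat shock and acute stress genes had 15 of 15 members above control (median 0.25, adjusted p = 3.19e-06). Of these, Ddit4 differed by 0.33 ± 0.10 and Sgk1 by 0.41 ± 0.12. With an estimated correlation the list had adjusted p = 0.474. Immediate early genes had 19 of 19 above (median 0.21, adjusted p = 2.82e-05) and circadian clock genes 13 of 17 (median 0.19, adjusted p = 0.000444), both with adjusted p = 0.474 with an estimated correlation. When adjusted over the list alone, 2 clock genes rose, and 0 genes of the heat shock and acute stress list or the immediate early list passed. These 3 calls held with each library left out. Neuropeptide genes had 15 of 17 members below control (median -0.36, adjusted p = 0.002), with Tac1 at -0.86 ± 0.47. Striatum markers had 12 of 14 below (median -0.51, adjusted p = 0.00229) and interneuron markers 13 of 15 (median -0.29, adjusted p = 0.0152). When adjusted over each list alone, 0 members of the 3 lists passed. Their adjusted p with an estimated correlation was 0.474, 0.679 and 0.65. The striatum score of control 2 was 1.10, while the other 9 hippocampus libraries lay between -0.31 and 0.15. Without control 2 the striatum median was -0.09 with adjusted p = 0.33. Besides those of neuropeptides and interneurons, the calls of amygdala nuclei, hypothalamus, GABA, glutamate and oxidative phosphorylation genes also ended (adjusted p from 0.0579 to 0.34).

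The other called lists of hippocampus NCoR1-KO moved less. Genes of mural cells, fibroblasts and meninges had 14 of 15 members above control, with Lum at 0.52 ± 0.19 (median 0.26, adjusted p = 0.0107), and PPAR targets 18 of 21 (median 0.08, adjusted p = 0.0184). Oxidative phosphorylation genes had 27 of 28 (median 0.03, adjusted p = 0.0213) and thyroid hormone induced genes 14 of 18 (median 0.13, adjusted p = 0.0249), with Klf9 at 0.17 ± 0.05. With an estimated correlation their adjusted p was 0.679, 0.679, 0.763 and 0.506. Amygdala nuclei markers had 12 of 16 below control, with Gpr101 at -0.94 ± 0.41, and 1 that fell when adjusted over the list alone (median -0.28, adjusted p = 0.0184). Microglia genes had 12 of 15 below (median -0.11, adjusted p = 0.0248) and hypothalamus genes 5 of 5 (median -0.70, adjusted p = 0.0248), with Hap1 at -0.90 ± 0.36. With an estimated correlation their adjusted p was 0.474, 0.736 and 0.474. Glutamate genes had 16 of 25 below (median -0.06, mean -0.21, adjusted p = 0.0318), and GABA genes 14 of 21 (median -0.03, mean -0.16, adjusted p = 0.0457). Both had adjusted p = 0.474 with an estimated correlation. Genes longer than 100 kb had 1376 of 2230 below control (median -0.04, adjusted p = 0.00656; adjusted p = 0.679 with an estimated correlation). The call ended without NCoR1-KO 1 (adjusted p = 0.115) and with the length and GC trend removed, where the median turned to 0.002 (adjusted p = 0.146). Besides control 2, the other calls of this group ended without NCoR1-KO 3 for mural cells (adjusted p = 0.0849), PPAR targets (adjusted p = 0.355), microglia (adjusted p = 0.181), hypothalamus (adjusted p = 0.0907), glutamate (adjusted p = 0.123), GABA (adjusted p = 0.146) and interneuron genes (adjusted p = 0.146). This library had a choroid plexus score of 2.73, while the other 9 hippocampus libraries lay between -1.73 and 1.83. With that score as a covariate, chosen after seeing the data like the other scores, the thyroid hormone, GABA, interneuron, glutamate and PPAR calls ended (adjusted p from 0.0592 to 0.0981). The oligodendrocyte score ended the thyroid hormone, GABA and glutamate calls (adjusted p from 0.0843 to 0.204), and the striatum score the GABA, neuropeptide, oxidative phosphorylation, amygdala nuclei, striatum and hypothalamus calls (adjusted p from 0.0747 to 0.747). They also ended without NCoR1-KO 1 for amygdala nuclei, thyroid hormone, glutamate and GABA genes (adjusted p from 0.0532 to 0.0993). Without control 3 they ended for PPAR, thyroid hormone, microglia and GABA genes (adjusted p from 0.0503 to 0.0805), and without control 1 for glutamate genes (adjusted p = 0.062). Quantile normalization ended the thyroid hormone and oxidative phosphorylation calls (adjusted p = 0.104 and adjusted p = 0.312). A filter at a mean of 5 TPM ended the PPAR call (adjusted p = 0.0548) and a pseudocount of 0.1 the GABA call (adjusted p = 0.0511). Without control 4 the microglia and oxidative phosphorylation calls ended (adjusted p = 0.195 and adjusted p = 0.0591), without NCoR1-KO 2 the oxidative phosphorylation call (adjusted p = 0.094), and without 1 of the 3 SMRT-KO libraries the GABA call (adjusted p from 0.0524 to 0.0691). Without hippocampus SMRT-KO 3 the glutamate call ended (adjusted p = 0.0513). The lists that were not called had adjusted p from 0.0685 to 0.839.

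In hippocampus SMRT-KO no single gene passed. At the preset correlation cholesterol synthesis genes lay above control as a group and inflammation and interferon genes below, and both calls ended with an estimated correlation (adjusted p = 0.685). Dhcr7, an enzyme of cholesterol synthesis, was at 52.6 ± 4.37 TPM against 42.7 ± 3.60 TPM in control (log2 difference 0.29 ± 0.08, n = 3 against 4), and Sqle was at 116 ± 7.91 against 96.8 ± 10.1 TPM (0.26 ± 0.09). The interferon-induced Isg15 was at 1.91 ± 0.491 against 5.10 ± 2.02 TPM (-1.02 ± 0.30), and Irf7, an interferon regulator, differed by -0.70 ± 0.24. Limma called 0 of 14501 genes. There were 813 at an unadjusted p under 0.05, 309 higher and 504 lower, and the smallest adjusted p was 0.779. The libraries did not overlap for 693 genes, 4.78%, where chance gives 5.71%. Of the genes nearest to passing, the neurofilament gene Nefm was at 203 ± 26.8 against 145 ± 8.80 TPM (0.48 ± 0.08). Rgs8, Fndc5 and Pcsk2 differed by 0.34 ± 0.07, 0.35 ± 0.07 and 0.28 ± 0.06. The transcription factor Mef2c was at 57.7 ± 6.95 against 80.7 ± 10.4 TPM (-0.48 ± 0.10), and Mertk, a receptor kinase, differed by -0.27 ± 0.06. Rn45s was at 11680 ± 3340 against 24700 ± 5950 TPM (-1.09 ± 0.25), and in hippocampus NCoR1-KO it differed by -0.93 ± 0.25. The count was 1, Snap25, without SMRT-KO 3 or without SMRT-KO 2 and 3.

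Camera called 14 of 41 lists in hippocampus SMRT-KO and 0 with an estimated correlation. Cholesterol synthesis genes had 23 of 23 members above control (median 0.25, adjusted p = 3.79e-12; adjusted p = 0.685 with an estimated correlation). Inflammation and interferon genes had 15 of 17 below (median -0.30, adjusted p = 7.78e-05; adjusted p = 0.685 with an estimated correlation). The score of this list was 0.55 in control 1 and between -0.04 and 0.06 in the other controls, and without control 1 the median was -0.19. Both calls held with each library left out, and 0 members of either passed when adjusted over the list alone. Oligodendrocyte and myelin genes had 18 of 18 above, with the iron carrier Trf at 0.54 ± 0.36 (median 0.40, adjusted p = 5.01e-05; adjusted p = 0.842 with an estimated correlation). Thalamus markers had 10 of 12 above (median 0.61, adjusted p = 0.0133; adjusted p = 0.842 with an estimated correlation). SMRT-KO 2 scored 2.15 for thalamus and 0.88 for oligodendrocytes. Without it the oligodendrocyte median was 0.07 (adjusted p = 0.241) and the thalamus median -0.24. The thalamus marker Tcf7l2 went from 1.11 ± 0.72 to -0.08. Dentate gyrus markers had 11 of 12 below (median -0.23, adjusted p = 0.0146; adjusted p = 0.842 with an estimated correlation), with C1ql3 at -0.38 ± 0.13. SMRT-KO 3 scored -0.59 for dentate gyrus and -0.63 for oligodendrocytes, and the dentate call ended without it (adjusted p = 0.66) and without control 1 or 4 (adjusted p = 0.0655 and adjusted p = 0.0701).

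The other called lists of hippocampus SMRT-KO had adjusted p = 0.0146 for 6 lists. CA field genes had 11 of 17 above control and 1 that rose when adjusted over the list alone (median 0.13), with Bok at 0.56 ± 0.12. Thyroid hormone induced genes had 10 of 18 above and 3 that rose when adjusted over the list alone (median 0.11), with the neurofilament gene Nefh at 0.90 ± 0.22. Oxidative phosphorylation genes had 19 of 28 above (median 0.03), and neuropeptides 13 of 17 below with Nts at -1.42 ± 0.47 (median -0.52). Cortex layer markers had 11 of 15 below (median -0.25) and sex-linked genes 4 of 5 below, 2 of which fell when adjusted over the list alone (median -0.29). Amygdala nuclei markers had 14 of 16 below (median -0.31, adjusted p = 0.0133). Circadian clock genes had 14 of 17 below with Tef at -0.13 ± 0.06 (median -0.10, adjusted p = 0.0273), and immediate early genes 17 of 19 below with Egr4 at -0.39 ± 0.20 (median -0.20, adjusted p = 0.0349). With an estimated correlation the adjusted p of these 9 lists lay between 0.685 and 0.842. Without SMRT-KO 2 the thyroid hormone, amygdala nuclei, neuropeptide and immediate early calls ended (adjusted p from 0.0524 to 0.703), and the thyroid hormone median turned to -0.015. Without SMRT-KO 1 the cortex, CA field, neuropeptide, clock and immediate early calls ended (adjusted p from 0.0628 to 0.275), and without SMRT-KO 3 the CA field, sex-linked, clock and oxidative phosphorylation calls (adjusted p from 0.143 to 0.447). Without control 2 the calls of CA field, neuropeptide, amygdala nuclei, oxidative phosphorylation, clock and immediate early genes ended (adjusted p from 0.0616 to 0.453), with an immediate early median of -0.07. Without control 1 the sex-linked and clock calls ended (adjusted p = 0.0531 and adjusted p = 0.0676), and without control 4 the oxidative phosphorylation call (adjusted p = 0.0701). Quantile normalization ended the CA field, thyroid hormone and oxidative phosphorylation calls (adjusted p from 0.0829 to 0.736), and a filter at a mean of 5 TPM the cortex, neuropeptide and immediate early calls (adjusted p from 0.0646 to 0.0818). With the oligodendrocyte score as a covariate the thyroid hormone, immediate early, neuropeptide, amygdala nuclei, cortex, oligodendrocyte and thalamus calls ended (adjusted p from 0.057 to 0.737). The striatum score ended the clock, immediate early, oxidative phosphorylation and CA field calls (adjusted p from 0.0847 to 0.175), and the choroid plexus score the first 3 of these (adjusted p from 0.0502 to 0.0667). The lists that were not called had adjusted p from 0.0681 to 0.977.

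**Figure D2:**
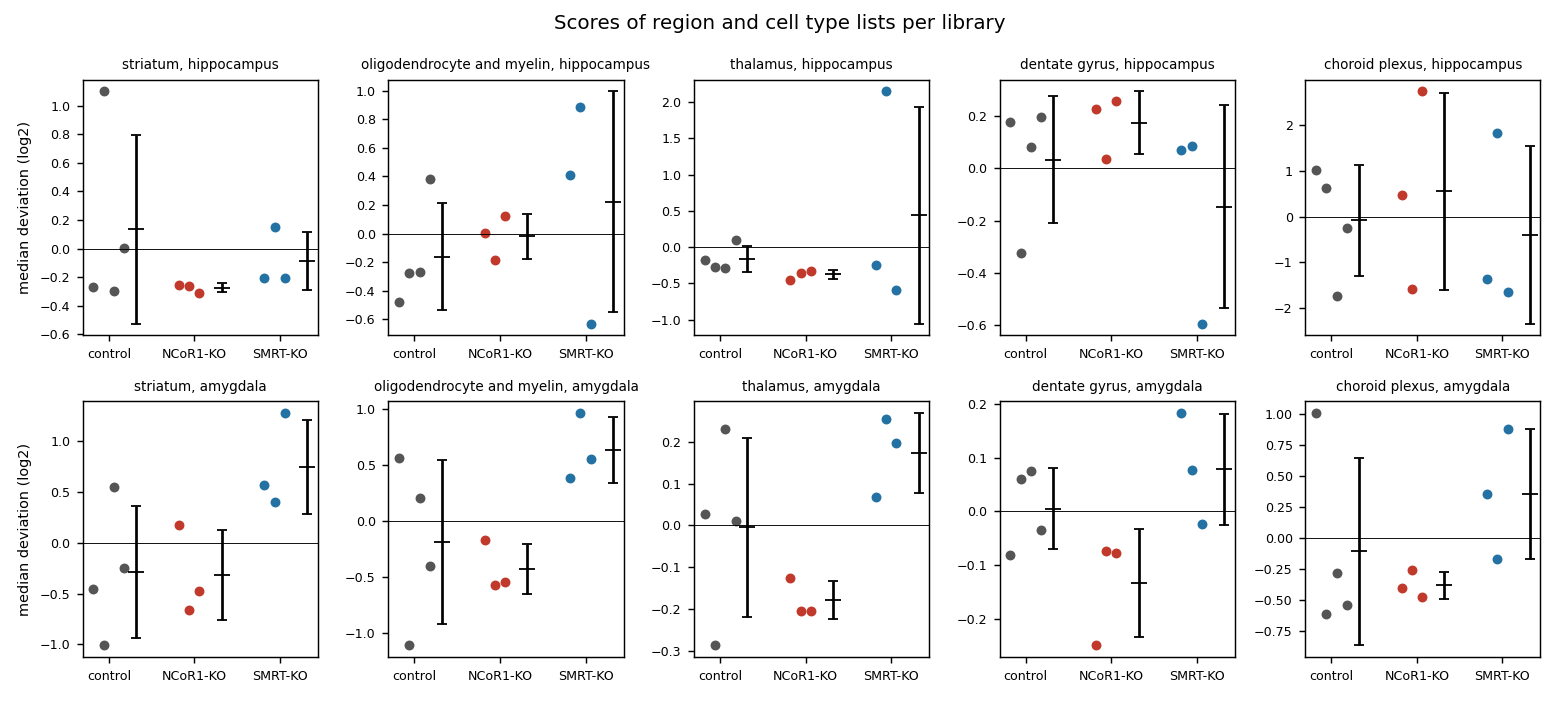
Score (vertical axis, median log2 deviation from the tissue mean) of 5 marker lists in each library of hippocampus and amygdala, by genotype; points are libraries and black bars are mean ± SD. Hippocampus SMRT-KO 2 stands apart for thalamus at 2.15 and control 2 for striatum at 1.10, and the 3 amygdala SMRT-KO libraries lie above 0 for striatum and oligodendrocyte genes.

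In amygdala NCoR1-KO, 60 of 14606 genes changed, 58 of them lower. Bmpr2, a receptor for bone morphogenetic proteins, fell from 49.2 ± 15.0 TPM (SD, n = 4) to 12.6 ± 2.88 TPM (SD, n = 3), a log2 change of -1.86 ± 0.21 (adjusted p = 0.0116). Kcnma1, a calcium-activated potassium channel, fell from 72.8 ± 12.3 to 33.2 ± 3.95 TPM (-1.10 ± 0.11, adjusted p = 0.00732). Erbb4, a neuregulin receptor, fell from 16.2 ± 7.83 to 3.38 ± 0.520 TPM (-1.85 ± 0.30, adjusted p = 0.0344), and Grin2a, an NMDA receptor subunit, from 22.5 ± 8.58 to 6.38 ± 0.823 TPM (-1.59 ± 0.26, adjusted p = 0.0341). Lnpep, an aminopeptidase, fell by 2.02 ± 0.32 and the nuclear receptor gene Rora by 0.87 ± 0.11 (adjusted p = 0.0308 and adjusted p = 0.0162). The genes that rose were Ldb2, from 64.6 ± 1.55 to 84.5 ± 1.97 TPM (0.38 ± 0.06, adjusted p = 0.0291), and Snap47, from 443 ± 11.5 to 513 ± 5.41 TPM (0.21 ± 0.04, adjusted p = 0.0441). Glt1d1 and Bscl2 were next and did not pass (0.27 ± 0.05 and 0.23 ± 0.05). Zbed6 fell by 2.12 ± 0.26, from 25 ± 9.29 to 4.74 ± 1.13 TPM (adjusted p = 0.0162). Its reads are uncertain, since it lies inside Zc3h11a on the same strand, which was at 95.0 ± 4.36 TPM in control and 96.4 ± 1.10 TPM in NCoR1-KO.

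The 58 lower genes of amygdala NCoR1-KO were long. Their median transcript was 10260 nt against 3149 nt for all tested genes, their median 3′ UTR 5642 nt against 1173 nt, and 38 of them spanned more than 100 kb. Amygdala NCoR1-KO 1 stood apart in this respect: across genes, its deviations correlated with transcript length at rho = -0.44 and with GC content at rho = 0.39, while the other 9 amygdala libraries lay between -0.08 and 0.23 for length and between -0.32 and 0.12 for GC. The fold changes correlated with length at rho = -0.22, and at rho = -0.05 without this library. Their median deviation was -0.75, -0.52 and -0.48 in amygdala NCoR1-KO 1, 2 and 3, between 0.00 and 0.34 in the amygdala controls and between 0.32 and 0.45 in amygdala SMRT-KO. In hippocampus the same 58 genes ranged from -0.13 to 0.60 within control, from -0.52 to 0.01 within NCoR1-KO and from -0.62 to 0.43 within SMRT-KO. With the trend in transcript length and GC content removed, an alternative chosen after seeing the data, 20 genes changed, 19 of them shared with the 60. At an unadjusted p under 0.05 there were 1915 genes, 482 higher and 1433 lower. Groups did not overlap for 1769 genes, 12.1%, where chance gives 5.71%. Limma called 3 genes without control 1 (Kcnma1, Ncor1 and Snap25), 126 without control 2, 14 without control 3, 7 without NCoR1-KO 1 and 17 without NCoR1-KO 3. Without NCoR1-KO 2 limma called 0, with 1662 at an unadjusted p under 0.05. The count was 26, 24 and 10 without SMRT-KO 1, 2 and 3.

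Microglia genes lay lower as a group in amygdala NCoR1-KO, with 15 of 15 members below control (median -0.27, adjusted p = 2.22e-07; adjusted p = 0.648 with an estimated correlation). Over all genes 0 members passed, and 13 fell when adjusted over the list alone. The microglial receptors P2ry12 and Cx3cr1 were at 60.4 ± 4.80 against 82.2 ± 12.4 TPM (-0.43 ± 0.11) and 45.2 ± 1.34 against 57.2 ± 5.92 TPM (-0.33 ± 0.07). Cx3cr1 is uncertain because other genes overlap it on the same strand. Immediate early genes had 18 of 19 above, with Egr1 at 249 ± 32.8 against 181 ± 48.1 TPM (median 0.32, adjusted p = 8.62e-05). Heat shock and acute stress genes had 14 of 15 above with Hspa8 at 0.21 ± 0.08 (median 0.16, adjusted p = 0.000159). Clock genes had 14 of 17 above with Arntl at 34.0 ± 1.57 against 27.4 ± 1.53 TPM (median 0.10, adjusted p = 0.000254). All 3 had adjusted p = 0.648 with an estimated correlation. When adjusted over the list alone, 3 clock genes rose and 1 fell. From the immediate early list and the heat shock and acute stress list 0 genes passed. The calls of these 4 lists held with each library left out.

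Camera called 7 further lists in amygdala NCoR1-KO, for a total of 11 of 40, and 0 with an estimated correlation, where all had adjusted p = 0.648. Astrocyte genes had 13 of 15 below, of which 4 fell when adjusted over the list alone and Slc1a2, a glutamate transporter, also over all genes, from 1430 ± 100 to 1059 ± 52.6 TPM (list median -0.18, adjusted p = 0.00314). Endothelial genes had 12 of 13 below (median -0.20, adjusted p = 0.00379) and inflammation genes 15 of 16, with B2m at -0.35 ± 0.11 (median -0.39, adjusted p = 0.00586). Oligodendrocyte precursor genes had 12 of 12 below, of which 2 fell when adjusted over the list alone (median -0.14, adjusted p = 0.0464). Oxidative phosphorylation genes had 24 of 28 above (median 0.05, adjusted p = 0.000146). Synaptic vesicle genes had 15 of 19 above, of which 3 rose and 1 fell when adjusted over the list alone and 1, Snap25, fell over all genes (median 0.12, adjusted p = 0.00287). Of 2232 genes longer than 100 kb, 38 fell and 1 rose over all genes, and 126 fell and 4 rose when adjusted over the list alone (median -0.07, adjusted p = 0.000146). The long-gene call ended without NCoR1-KO 1 (adjusted p = 0.0651) and with the length and GC trend removed (adjusted p = 0.465). Without control 1 the astrocyte, endothelial, inflammation and precursor calls ended (adjusted p from 0.0504 to 0.232), and without control 3 the precursor call (adjusted p = 0.0783). Without NCoR1-KO 1 the oxidative phosphorylation call ended (adjusted p = 0.0526), without NCoR1-KO 2 the endothelial and inflammation calls (adjusted p = 0.0939 and adjusted p = 0.082), and without NCoR1-KO 3 the astrocyte, inflammation, precursor and vesicle calls (adjusted p from 0.0505 to 0.207). Quantile normalization ended the vesicle and oxidative phosphorylation calls (adjusted p = 0.26 and adjusted p = 0.248), and a pseudocount of 0.1 the precursor call (adjusted p = 0.0507), which each of the 3 scores as a covariate also ended (adjusted p from 0.0502 to 0.12). The lists that were not called had adjusted p from 0.0537 to 0.975.

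In amygdala SMRT-KO, 16 of 14606 genes changed, 7 higher and 9 lower. Kcnh5, a voltage-gated potassium channel, rose from 5.20 ± 2.67 TPM (SD, n = 4) to 21.8 ± 6.58 TPM (SD, n = 3), a log2 change of 1.93 ± 0.30 (adjusted p = 0.0473). Grm3, a metabotropic glutamate receptor, rose from 38.7 ± 6.46 to 77.3 ± 12.2 TPM (0.98 ± 0.13, adjusted p = 0.0441). Fat3, a large cadherin, rose from 14.5 ± 3.03 to 26.4 ± 1.00 TPM (0.84 ± 0.13), Rora from 18.2 ± 2.25 to 31.0 ± 2.98 TPM (0.74 ± 0.11) and Clstn2 from 44.7 ± 2.24 to 62.5 ± 5.98 TPM (0.47 ± 0.07), the last 3 with adjusted p = 0.0473. Kctd16, an auxiliary subunit of GABA-B receptors, rose from 19.7 ± 3.84 to 42.4 ± 3.72 TPM (1.08 ± 0.13, adjusted p = 0.035). It is uncertain because it overlaps 2900055J20Rik on the same strand. Besides Snap25, Rtbdn fell from 3.72 ± 0.479 to 1.42 ± 0.361 TPM (-0.97 ± 0.13, adjusted p = 0.0441). Mov10, an RNA helicase, Tle2, a corepressor, and Snhg11 fell by 0.67 ± 0.10, 0.64 ± 0.10 and 0.49 ± 0.07 (adjusted p = 0.0473). All 7 higher genes spanned more than 100 kb, against 1 of the 9 lower ones. At an unadjusted p under 0.05 there were 3208 genes, 1230 higher and 1978 lower. Groups did not overlap for 2633 genes, 18%, where chance gives 5.71%. Limma called 1 gene, Snap25, without control 1, 2 or 4 or SMRT-KO 2, 57 genes without control 3 and 697 without SMRT-KO 1. It called 0 without SMRT-KO 3, with 2296 at an unadjusted p under 0.05, and 2, Snap25 among them, without NCoR1-KO 1, 2 or 3.

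Striatum and oligodendrocyte genes were higher as groups in amygdala SMRT-KO, with 15 of 15 and 18 of 18 members above control (medians 0.98 and 0.83, both adjusted p = 2.17e-08; adjusted p = 0.594 and adjusted p = 0.692 with an estimated correlation). Over all genes 0 members of either passed, and 14 striatum and 0 oligodendrocyte genes rose when adjusted over the list alone. The dopamine receptor Drd2 was at 30.6 ± 10.3 against 12.3 ± 8.93 TPM (1.44 ± 0.46) and Trf at 211 ± 50.6 against 117 ± 46.6 TPM (0.89 ± 0.27). Per library, the striatum score lay between 0.40 and 1.27 in SMRT-KO, between -1.01 and 0.55 in control and between -0.66 and 0.18 in NCoR1-KO. The oligodendrocyte score lay between 0.39 and 0.97 in SMRT-KO, between -1.11 and 0.56 in control and between -0.57 and -0.17 in NCoR1-KO. Without control 2, the lowest of these, the oligodendrocyte median was 0.523. With the striatum or the oligodendrocyte score as a covariate, both chosen after seeing the data, limma called 0 genes, with 1586 and 2270 at an unadjusted p under 0.05.

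Camera called 8 of 40 lists in amygdala SMRT-KO, all higher, and 0 with an estimated correlation, where the smallest adjusted p = 0.324. Voltage-gated channel genes had 24 of 32 above, of which 17 rose and 3 fell when adjusted over the list alone, with Kcnh7 at 1.82 ± 0.29 and Cacna1i at 0.59 ± 0.10 (median 0.20, adjusted p = 2.11e-06). Thyroid hormone induced genes had 13 of 18 above, of which 10 rose and 1 fell when adjusted over the list alone, with the synaptic scaffold gene Homer1 at 168 ± 28.2 against 108 ± 19.3 TPM and the interneuron gene Pvalb at 65.9 ± 32.7 against 23.3 ± 6.52 TPM (median 0.43, adjusted p = 0.000103). Cortex layer markers had 12 of 15 above, of which 6 rose when adjusted over the list alone, with Fezf2 at 0.60 ± 0.14 (median 0.33, adjusted p = 0.000106). Nuclear receptor genes had 19 of 30 above, of which 5 rose and 3 fell when adjusted over the list alone, and Rora also rose over all genes (median 0.14, adjusted p = 0.0133). These 4 lists had adjusted p = 0.324 with an estimated correlation. Their calls held with each library left out, as did those of striatum and oligodendrocyte genes. The lists are not exclusive, since the thyroid hormone list also holds the myelin gene Mbp. Whether these 4 calls are separate from the higher striatum and oligodendrocyte genes cannot be told, because those scores differ with the groups. Genes longer than 100 kb had 7 that rose and 1 that fell over all genes, and 84 that rose and 26 that fell when adjusted over the list alone (median 0.01, adjusted p = 0.011). Cholesterol synthesis genes had 18 of 23 above, with 0 passing when adjusted over the list alone (median 0.09, adjusted p = 0.0146). Both lists had adjusted p = 0.871 with an estimated correlation. The long-gene call ended without SMRT-KO 1 (adjusted p = 0.0778) and with the length and GC trend removed (adjusted p = 0.125). The cholesterol call ended without control 2 or 3 or SMRT-KO 2 (adjusted p from 0.0653 to 0.0769), and with the oligodendrocyte or striatum score as a covariate (adjusted p = 0.276 and adjusted p = 0.148). The lists that were not called had adjusted p from 0.0514 to 0.999.

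**Figure D3:**
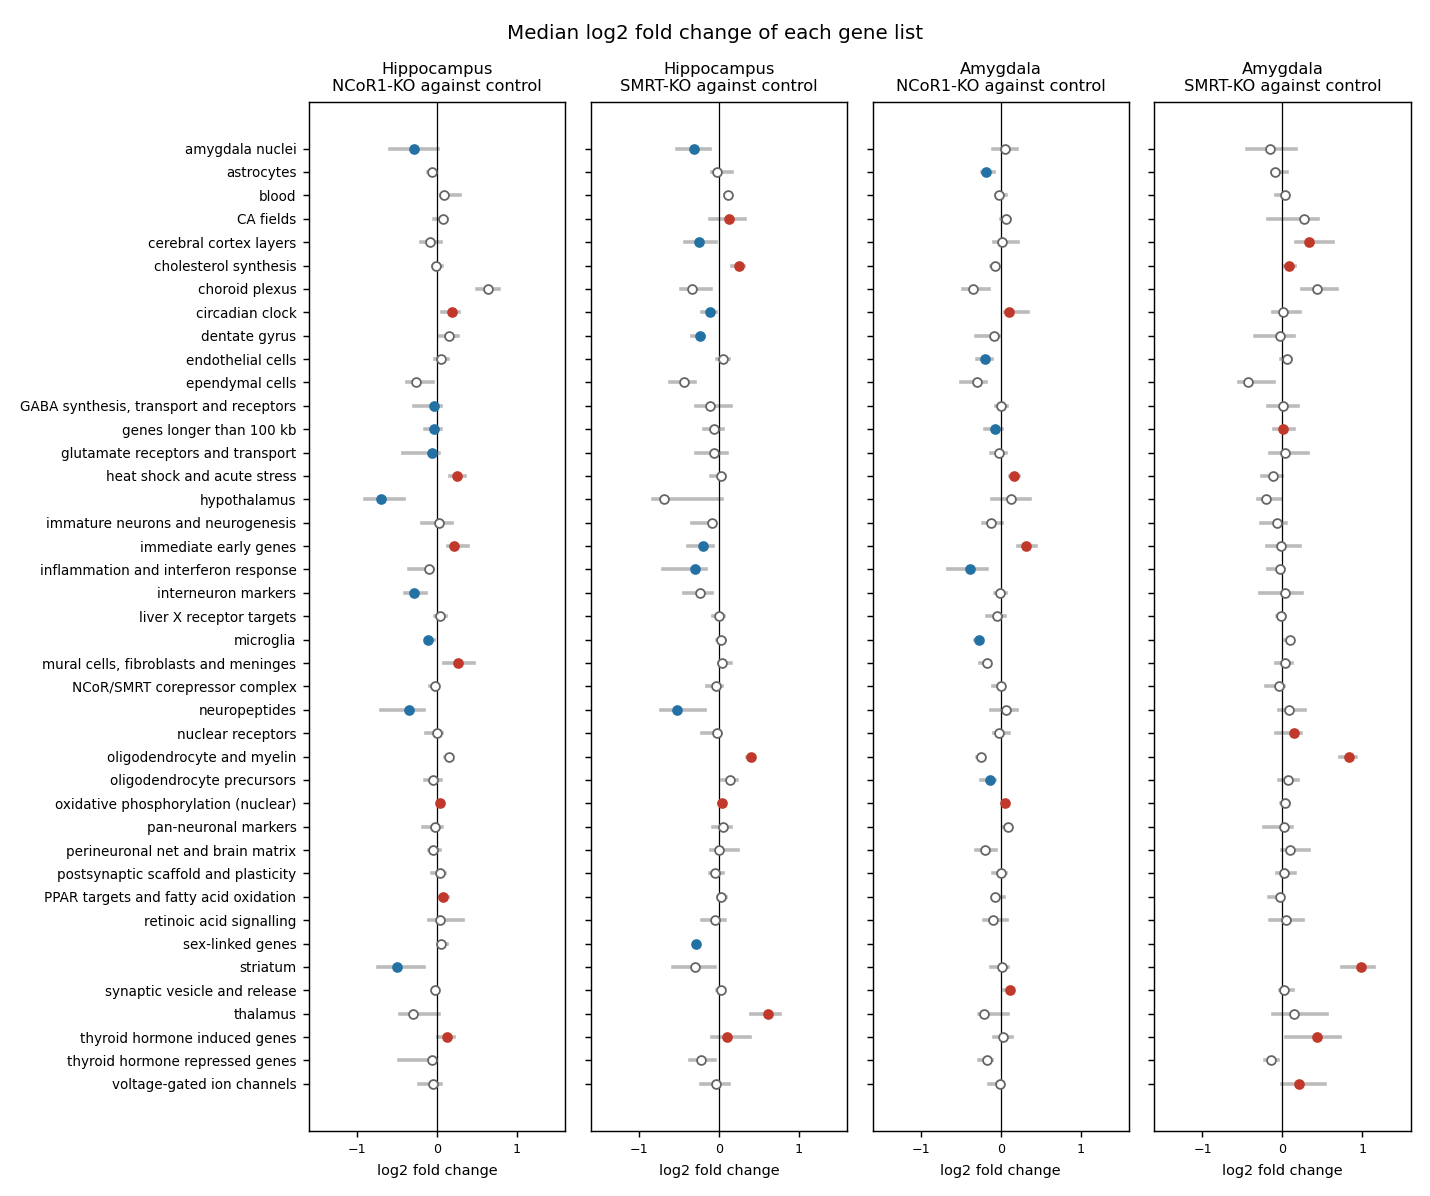
Median log2 fold change (horizontal axis) of each gene list for each knockout against control in both tissues; grey bars span the lower to the upper quartile of the members, and filled points are lists called higher (red) or lower (blue) by camera at the preset correlation, open points lists not called. In amygdala SMRT-KO all 8 called lists are higher, with striatum at 0.98 and oligodendrocyte genes at 0.83.

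Set directly against each other, the knockouts differed in 1679 amygdala genes, 735 higher and 944 lower in NCoR1-KO. Kcnma1 was at 33.2 ± 3.95 TPM in NCoR1-KO and 113 ± 1.47 TPM in SMRT-KO (log2 difference -1.74 ± 0.12, adjusted p = 0.000223, n = 3 against 3). Rora was at 9.45 ± 1.00 against 31.0 ± 2.98 TPM (-1.62 ± 0.12) and Bmpr2 at 12.6 ± 2.88 against 81.3 ± 3.58 TPM (-2.62 ± 0.23). The potassium channel gene Kcnq3 was at 23.0 ± 2.55 against 70.7 ± 8.11 TPM (-1.58 ± 0.14). In the other direction Barhl2, a homeobox gene, was at 4.94 ± 0.17 against 1.36 ± 0.586 TPM (1.36 ± 0.17, adjusted p = 0.00289). Cd200, a membrane protein that restrains microglia, was at 213 ± 11 against 138 ± 13.8 TPM (0.63 ± 0.09) and Ubap2l at 114 ± 4.68 against 88.7 ± 2.97 TPM (0.35 ± 0.05). Ncor1 differed by -1.73 ± 0.18 (adjusted p = 0.0013) and Snap25 by 0.08 ± 0.08 (adjusted p = 0.568). The 944 lower genes had a median span of 74880 bp and 367 exceeded 100 kb, while the 735 higher ones had a median span of 17040 bp, against 24850 bp for all tested genes. Groups did not overlap for 5611 genes, 38.4%, where chance gives 10%, and 4543 genes had an unadjusted p under 0.05. Genes are not independent, so this share alone does not tell an effect of the genotypes from a shift of whole libraries. The count was 647, 344 and 911 without NCoR1-KO 1, 2 and 3, and 335 and 246 without SMRT-KO 2 and 3. With the oligodendrocyte, striatum or choroid plexus score as a covariate it was 25, 16 and 573, with 4%, 6.25% and 39.8% of these higher in NCoR1-KO. Without NCoR1-KO 2 or SMRT-KO 3, 20.9% and 21.5% were higher. With the length and GC trend removed it was 1675, of which 60.2% were higher in NCoR1-KO, against 43.8% before.

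Camera called 12 of 40 lists between the amygdala knockouts, 11 of them lower in NCoR1-KO, and 0 with an estimated correlation, where all had adjusted p = 0.69. Oligodendrocyte genes were lower in 18 of 18, 4 over all genes and 18 when adjusted over the list alone (median -1.06, adjusted p = 1.31e-06). Microglia genes were lower in 15 of 15, 9 over all genes and 12 when adjusted over the list alone (median -0.36, adjusted p = 1.31e-06). Striatum markers were lower in 15 of 15, 2 over all genes and 10 when adjusted over the list alone (median -1.12, adjusted p = 0.000113). Perineuronal net genes were lower in 11 of 11, 4 over all genes and 5 when adjusted over the list alone (median -0.20, adjusted p = 0.00465). Voltage-gated channel genes were lower in 25 of 32 and 9 over all genes (median -0.21, adjusted p = 7.91e-05), and cholesterol synthesis genes in 20 of 23 and 1 (median -0.20, adjusted p = 0.00465). Endothelial genes were lower in 11 of 13 and 2 over all genes (median -0.26, adjusted p = 0.00821), thyroid hormone induced genes in 13 of 18 and 5 (median -0.49, adjusted p = 0.0362) and oligodendrocyte precursor genes in 10 of 12 and 1 (median -0.26, adjusted p = 0.0404). Cortex layer markers had 4 lower and 1 higher over all genes (median -0.43, adjusted p = 0.0157), and genes longer than 100 kb 367 lower and 44 higher (median -0.09, adjusted p = 8.26e-06). Heat shock and acute stress genes were higher in NCoR1-KO in 14 of 15, 1 over all genes and 4 when adjusted over the list alone (median 0.32, adjusted p = 0.00465). The lists that were not called had adjusted p from 0.064 to 0.938. In hippocampus limma called 0 of 14501 genes between the knockouts, with 956 at an unadjusted p under 0.05 and a smallest adjusted p of 0.42. Groups did not overlap for 1660 genes, 11.4%, where chance gives 10%. Ncor1 differed there by -1.24 ± 0.21 (adjusted p = 0.607).

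Snap25 was the 1 gene that fell in both amygdala knockouts, which share their controls, and 0 genes rose in both. Rora was the 1 gene that changed in opposite directions, lower in NCoR1-KO and higher in SMRT-KO. Across genes, which are not independent replicates, the fold changes of the 2 knockouts correlated with r = -0.132 in amygdala (rho = -0.034) and r = 0.368 in hippocampus (rho = 0.361). Unchanged groups simulated against the same controls, with noise drawn separately for each gene, gave mean r = 0.425 (highest 0.523) and r = 0.428 (highest 0.5). The real samples regrouped in seeded ways reached 0.807 in amygdala and 0.76 in hippocampus. The simulated spread is thus narrower than that of regrouped real samples, and the simulation serves as a reference for the mean only. The covariance was -0.00617 against a simulated 0.0104 in amygdala, a difference of -0.0166. It was 0.0138 against 0.0172 in hippocampus, a difference of -0.00342. With the 4 controls divided between the knockouts in 6 ways, r lay between -0.48 and -0.016 in amygdala and between -0.181 and 0.275 in hippocampus. Without amygdala NCoR1-KO 2 the amygdala r was 0.049.

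Ncor1 and Snap25 were lower in NCoR1-KO of both tissues. Of the 60 genes that changed in amygdala NCoR1-KO, 58 had the same direction in hippocampus, as did 9 of the 16 of amygdala SMRT-KO. With the libraries regrouped alike in both tissues, 2 of 35 splits gave 58 or more of the 60 amygdala genes of smallest p the same sign in hippocampus (median 41), and 25 of 35 gave 9 or more of 16 (median 11). The median hippocampus deviation of the 58 lower genes was -0.52 in NCoR1-KO 1, 0.01 in NCoR1-KO 2 and -0.04 in NCoR1-KO 3, against -0.13 in control 3. Over 14210 genes tested in both tissues, the fold changes correlated with r = 0.376 (rho = 0.247) for NCoR1-KO and r = 0.217 (rho = 0.274) for SMRT-KO, across genes that are not independent replicates. Without hippocampus NCoR1-KO 2 the first r was 0.245, and without hippocampus SMRT-KO 2 the second was 0.103. In the joint fit limma called 0 genes whose effect differed between the tissues for either knockout, with 522 and 1257 at an unadjusted p under 0.05 and smallest adjusted p of 0.998 and 0.12. The SMRT-KO count was 18 without hippocampus SMRT-KO 1, 3 without amygdala control 3 and 1 without amygdala SMRT-KO 1.

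Genes near a floxed locus can differ between strains, so changed genes within 10 Mb of Ncor1 were counted. Snap47, on chromosome 11 from 59407134 to 59451186, was the 1 changed gene among 255 near Ncor1 in amygdala NCoR1-KO, against 57 of 14200 elsewhere (two-sided Fisher's exact p = 1). Within 5 Mb it was 1 of 107 (Fisher's exact p = 0.351). In hippocampus NCoR1-KO limma called 0 of 247 such genes.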

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

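The tests of explanations in this part were all chosen after the results were seen, while the search for control libraries far from the other 3 was fixed beforehand. The search covered 273 values, each a gene or list score in the 4 controls of a tissue. In 14 of them the gap of 1 control to the nearest other, as a share of the range, exceeded Dixon's critical value. Chance gives about 1 in 20 for a single value. These values come from the same 4 controls per tissue and are not independent, so the share is a description only. The library was control 1 in 3 of the 14.

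In hippocampus, control 2 had Fosb at 11.9 TPM against 2.56 to 3.15 TPM in the other controls (gap 0.881 of the range) and Pvalb at 44.0 TPM against 55.4 to 57.3 TPM (0.872). Control 4 had Snap47 at 343 TPM against 386 to 391 TPM (0.913), and control 1 had Vcam1 at 34.7 TPM against 29.6 to 30.1 TPM (0.898). For list scores, control 2 stood apart for amygdala nuclei at 0.72 against 0.01 to 0.12 (gap 0.843), control 3 for genes longer than 100 kb at -0.01 against 0.04 (0.91), and control 1 for inflammation and interferon genes at 0.55 against -0.04 to 0.06 (0.835).

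In amygdala, control 4 had Hadhb at 83.7 TPM against 73.9 to 75.4 TPM (gap 0.842) and Sqle at 113 TPM against 99.1 to 101 TPM (0.864). Control 3 had Mov10 at 11.5 TPM against 13.7 to 14.0 TPM (0.891), Nefh at 36.2 TPM against 22.8 to 24.6 TPM (0.835) and Nefm at 168 TPM against 115 to 123 TPM (0.84). Control 2 had a score for heat shock and acute stress genes of 0.26 against -0.14 to -0.09 (0.868). Control 1 had Ncor1 at 71.3 TPM against 117 to 127 TPM (0.869).

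Ncor1 was low in control 1 of both tissues, at 63.5% of the other controls in hippocampus and 59% in amygdala, while NCoR1-KO lay at 38.3% and 29.1%. With the length and GC trend removed the deficits were -0.72 and -0.74 on the log2 scale, which argues against that trend. Of 14210 genes, 14 (0.0985%) were as low in control 1 of both tissues, but the value was noted for being low and libraries of the same number deviate together across tissues, so a low value by chance stays open. A knockout library labelled as control is argued against by Snap25, which in control 1 was at 98.9% and 93.1% of the other controls, 2236 and 1927 TPM against at most 1699 and 1228 TPM in any knockout library. An animal with 1 deleted Ncor1 allele may give such a level, but the labels do not give the genotype of single controls, so this stayed untested.

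Snap25 was lower in all 4 comparisons of a knockout with control. A loss of neurons is argued against by 13 other pan-neuronal markers, whose median differences were -0.001, 0.06, 0.09 and 0.02 (SD over markers 0.13, 0.17, 0.10 and 0.34). Single markers varied, and the lowest was at -0.63 in amygdala SMRT-KO, where Snap25 was at -0.85. In the other comparisons the lowest marker lay between -0.23 and -0.18. The length and GC trend is argued against by the Snap25 change after its removal, which was -0.79, -0.74, -0.71 and -0.84. The Cre allele inserted at Snap25 is a candidate explanation, for which the knockouts should be alike, and they differed by at most 0.08 on the log2 scale. In hippocampus that difference ran from -0.17 without SMRT-KO 2 to 0.15 without SMRT-KO 3, so its size there rests on libraries that offset each other. It cannot be told apart from the knockouts themselves, because the labels do not say whether the controls carried Cre.

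Many genes differed between the amygdala knockouts, 1679 in all. The length and GC trend is argued against as the whole cause, since 1143 of these genes were also called with it removed, and a single library is argued against by the 246 genes called without the library that mattered most. A different amount of neighbouring striatum or of oligodendrocytes in the dissected tissue may contribute: among the controls, the slopes of the called genes on the striatum and oligodendrocyte scores correlated with the difference between the knockouts at r = -0.681 and r = -0.561. Over the 24 orders of the 4 controls these had exact two-sided permutation p = 0.125 and p = 0.208 (adjusted p = 0.365 for both over 7 lists tried), thalamus and immediate early genes had r = -0.695 and r = 0.606 (adjusted p = 0.365), and astrocyte, choroid plexus and pan-neuronal genes r = -0.283, r = -0.137 and r = -0.066 (adjusted p from 0.826 to 0.875). Neither source can be told apart from an effect of the genotypes, because 4 controls are too few and the scores differ with the groups.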

How the results depend on the processing

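The alternatives named as chosen after seeing the data are the removal of the length and GC trend, the omission of control 1 or of hippocampus SMRT-KO 2 and 3, and the marker scores as covariates, and all others were fixed beforehand. Where no reason is given, the cause was not tested. Removing mitochondrial genes and a sex covariate were not run, since the tables listed none of these genes and all 20 libraries had male levels of Xist and Ddx3y. Depth is unknown, so its limits could not be stated.

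The count for amygdala NCoR1-KO, 60, was 16 with no filter, 4 with only the groups compared (Cyp26b1, Kcnma1, Ncor1 and Snap25, the first chosen after its values were seen), 20 with the trend removed, 3 without control 1, and 28, 39 and 9 with the oligodendrocyte, striatum and choroid plexus score. With libraries left out in turn it ranged from 0 (1662 at an unadjusted p under 0.05 by limma) to 126. The count for amygdala SMRT-KO, 16, was 2 with no filter (Snap25 among them), 143 with a mean of 5 TPM, 4 with median ratio scaling (Grm3, Kctd16 and Snap25 among them), 2 with only the groups compared (Snap25 among them), 129 with the trend removed, 1 without control 1 (Snap25), 0 with the oligodendrocyte or striatum score and 1 with the choroid plexus score. Left-out libraries gave 0 to 697. Quantile normalization called 14 genes, 64.3% of them higher, against 43.8%. The count between the amygdala knockouts, 1679, was 25, 16 and 573 with the oligodendrocyte, striatum and choroid plexus score, and 246 to 2218 with libraries left out. With the trend removed it was 1675, 60.2% of them higher, against 43.8%.

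In hippocampus the NCoR1-KO count of 0 was 1 with quantile normalization, with only the groups compared, without SMRT-KO 2 and 3 and with the oligodendrocyte score, each time Snap25, and 0 to 1 with libraries left out. The SMRT-KO count of 0 was 1 with quantile normalization and without SMRT-KO 2 and 3, again Snap25, and 0 to 1 with libraries left out. Between the hippocampus knockouts the count of 0 was 5 with only the groups compared (2610507I01Rik, 8430408G22Rik, AA465934, Gm1821 and Mrpl55, chosen after their values were seen), 1 with the striatum score and 0 to 1 with libraries left out. The main counts had 658, 813 and 956 genes at an unadjusted p under 0.05.

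Ncor1 in amygdala NCoR1-KO, -1.57, ranged from -1.75 to -1.48 with libraries left out. The count near Ncor1 in amygdala, 1, was 0 with no filter, quantile normalization, the trend removed, control 1 omitted and each of the 3 scores, and 0 to 2 with libraries left out. The count of genes whose SMRT-KO effect differs between tissues, 0, was 1 with no filter and 0 to 18 with libraries left out.

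The hippocampus correlation of both knockouts, 0.368, had a median of 0.013 with the controls divided, was 0.132 without SMRT-KO 2 and 3, and ranged from 0.254 to 0.488 with libraries left out. The amygdala correlation, -0.132, had a median of -0.275 with the controls divided, was -0.055 without control 1, 0.097 and 0.183 with the oligodendrocyte and striatum score, and ranged from -0.211 to 0.049. The correlation between tissues was 0.318 without control 1 and 0.245 to 0.409 with libraries left out for NCoR1-KO (0.376), and 0.262 and 0.103 to 0.30 for SMRT-KO (0.217). Camera with an estimated correlation called 0 lists in each comparison. The hippocampus NCoR1-KO lists, 16, ranged from 8 to 21 with libraries left out, and the amygdala NCoR1-KO lists, 11, were 7 without control 1 and ranged from 7 to 14. The amygdala SMRT-KO lists, 8, were 16 with the oligodendrocyte score.

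With the replicate number as a block, the amygdala NCoR1-KO count was 41, the SMRT-KO count 4 (Grin2a, Itpr1, Kctd16 and Snap25, Itpr1 chosen after its values were seen) and the count between the knockouts 854. The count near Ncor1 was 0. The correlations were 0.474 in hippocampus, -0.001 in amygdala, and 0.304 and 0.282 between tissues. Within a tissue the numbers did not pair libraries of different genotypes, since 2 of 9 same-numbered pairs deviated together at r over 0.1, in hippocampus and in amygdala. Between tissues 7 of 10 pairs of the same genotype and number did (0.001 to 0.48, median 0.147), against 2 of 24 with other numbers (median -0.0825), so the tissues are not independent. With these pairs as a block (consensus correlation 0.185) the joint fit still called 0 genes for either knockout.

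The sign changed for these values. Snap25 between the amygdala knockouts, 0.08, was -0.01 with the oligodendrocyte or striatum score, and between the hippocampus knockouts, -0.03, was 0.01 with quantile normalization, 0.05 without SMRT-KO 2 and 3, 0.02 with the choroid plexus score and -0.17 to 0.15 with libraries left out. Ncor1 in SMRT-KO was -0.03 in amygdala and -0.14 in hippocampus without control 1, -0.10 in hippocampus with the oligodendrocyte score, and -0.03 to 0.25 and -0.14 to 0.12 with libraries left out. In hippocampus SMRT-KO, Tcf7l2 ranged from -0.08 to 1.79, the oxidative phosphorylation median was -0.019 without SMRT-KO 2 and 3 and -0.007 to 0.064 with libraries left out, and the thalamus median -0.066 and -0.239 to 1.142. There the thyroid hormone median was -0.013 with the oligodendrocyte score and -0.015 to 0.227 with libraries left out, and the dentate gyrus median 0.029 without SMRT-KO 2 and 3 and -0.385 to 0.002. The NCoR1-KO median of genes longer than 100 kb was 0.002 in hippocampus (-0.058 to -0.014 with libraries left out) and 0.004 in amygdala (-0.095 to -0.039) with the trend removed. In amygdala SMRT-KO the oligodendrocyte median was -0.005 (0.523 to 1.064) and the striatum median -0.008 (0.797 to 1.262) with the list's own score as covariate, which fixes them near 0. Of the 880 values of 49 gene lists under alternatives fixed beforehand, 737 kept direction and call, 139 lost the call and 4 reversed, and of 275 under those chosen later 218 did, 49 lost it and 8 reversed. Of the 2305 values of 136 named genes under the former, 2105 kept both, 176 lost the call, 18 gained it and 6 reversed, and of 751 under the latter 666, 74, 4 and 7. A named gene without a call in the main fit that stayed without one is counted as kept. In hippocampus no gene had a call in the main fit, so the share of named genes kept is not a measure of how well calls held.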

Other observations

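The tests of other splits of the samples were fixed beforehand, except those made alike in both tissues, while the genes described from hippocampus below were chosen after the called lists were seen. Between the hippocampus knockouts, the lists of smallest p at the preset correlation were cholesterol synthesis, immediate early and circadian clock genes, an order that an estimated correlation does not keep and that is not one of size. Cholesterol synthesis genes were lower in NCoR1-KO than in SMRT-KO for 23 of 23 members (median -0.27, adjusted p = 3.58e-11), and 0 passed over all genes. Immediate early genes were higher in NCoR1-KO for 18 of 19 (median 0.42, adjusted p = 2.55e-08), and clock genes for 15 of 17, of which 8 were higher when adjusted over the list alone (median 0.26, adjusted p = 8.53e-07). All 3 had adjusted p = 0.723 with an estimated correlation. At the preset correlation the clock list lay above control in NCoR1-KO of both tissues and below it in hippocampus SMRT-KO, and these calls ended with an estimated correlation too. The SMRT-KO call also ended without control 1 or 2 or SMRT-KO 1 or 3 (adjusted p from 0.0676 to 0.357), with a median of -0.016 without SMRT-KO 3.

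Camera called 9 further lists between the hippocampus knockouts, for 12 of 41, and 0 with an estimated correlation. Higher in NCoR1-KO were dentate gyrus markers in 12 of 12 (median 0.42, adjusted p = 0.000125) and heat shock and acute stress genes in 14 of 15 (median 0.32, adjusted p = 0.000823). Sex-linked genes were higher in 4 of 5 (median 0.34, adjusted p = 0.000823) and inflammation genes in 15 of 17 (median 0.22, adjusted p = 0.0222). When adjusted over the list alone, 1 heat shock and acute stress gene and 4 sex-linked genes were higher. Lower were thalamus markers in 12 of 12 (median -0.86, adjusted p = 0.000271), microglia genes in 13 of 15 (median -0.10, adjusted p = 0.00221), pan-neuronal genes in 12 of 14, of which 2 were lower when adjusted over the list alone (median -0.06, adjusted p = 0.00507), oligodendrocyte precursor genes in 12 of 12 (median -0.16, adjusted p = 0.00723) and oligodendrocyte genes in 18 of 18 (median -0.25, adjusted p = 0.0157). With an estimated correlation these 9 had adjusted p from 0.723 to 0.905. SMRT-KO 2, with a thalamus score of 2.15, and SMRT-KO 3, with a dentate gyrus score of -0.59, stand apart in the same lists. The lists that were not called had adjusted p from 0.0956 to 0.884.

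The libraries of each comparison were also split in every other way into groups of the same sizes. For amygdala NCoR1-KO, 3 of 35 splits called at least the real 60 genes, with 84 in the highest other split, which put control 2 with NCoR1-KO 2 and 3. The next, with 65 genes, set controls 1, 3 and 4 against control 2 and all NCoR1-KO libraries. For amygdala SMRT-KO, 2 of 35 called at least 16, with 26 in the highest other split. It set controls 1, 2 and 4 against control 3 and all SMRT-KO libraries. These other splits kept most of each real group together. By the shares of splits, chance was not excluded for either count. The counts of called lists were reached by 20 of 35 splits for amygdala NCoR1-KO (real 11, highest other 17), 33 of 35 for amygdala SMRT-KO (real 8, highest other 19), 5 of 35 for hippocampus NCoR1-KO (real 16, highest other 19) and 21 of 35 for hippocampus SMRT-KO (real 14, highest other 26), so chance was not excluded for these either. The real count of 0 genes was reached by all 35 splits in hippocampus for each knockout, with 1 and 223 in the highest other splits, and since every split reaches 0 these tests decide nothing. The split with 223 genes put control 4 with SMRT-KO 1 and 2. The counts of changed genes near Ncor1 were reached by 3 of 35 splits for amygdala NCoR1-KO (real 1, highest other 1) and by 35 of 35 for hippocampus NCoR1-KO (real 0, highest other 0), where the second decides nothing.

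Between the amygdala knockouts, 1 of 10 splits, the real one, called 1679 genes, and the highest other split called 0. Between the hippocampus knockouts, 10 of 10 splits reached the real count of 0, as any split must, and the highest other called 1. With 10 splits a share under 0.05 is not possible. Correlations of the fold changes of both knockouts were reached in size by 67 of 100 drawn splits in hippocampus (real 0.368, highest other 0.76). In amygdala 87 of 100 reached it (real -0.132, highest other 0.807). Size was counted from 0, while shared controls alone gave a simulated mean r of 0.428 in hippocampus and 0.425 in amygdala. These counts therefore cannot tell whether a correlation is unusually low, and chance was not excluded. Of the correlations between tissues, that of NCoR1-KO was reached by 4 of 100 splits drawn separately in each tissue (real 0.376, highest other 0.455) and that of SMRT-KO by 16 of 100 (real 0.217, highest other 0.462). Separate draws break the link between hippocampus and amygdala libraries of the same genotype and number, of which 7 of 10 pairs deviated together. With the same regrouping in both tissues, 7 of 35 splits reached the NCoR1-KO correlation (highest other 0.527) and 16 of 35 that of SMRT-KO (highest other 0.456), so chance was not excluded for either. The counts of 0 genes that differ between tissues were reached by 100 of 100 splits for both knockouts, as any count reaches 0, with 16 and 747 genes in the highest other splits. The 58 of 60 amygdala NCoR1-KO genes with the same sign in hippocampus were reached by 2 of 35 splits made alike in both tissues (highest other 58), and the 9 of 16 of SMRT-KO by 25 of 35 (highest other 16), so chance was not excluded.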
